A study of Homo sapiens with 2 samples.

How the data were processed

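The series holds 2 libraries from PLC/PRF/5, an established human liver cancer cell line, transduced with a lentivirus that overexpresses the zinc finger protein ZFP64. One library came from chromatin precipitated with an antibody against the Flag tag (the Flag ChIP) and 1 from chromatin without precipitation (the input). Neither has a replicate, and no Flag ChIP from cells without the tagged protein was used here. Per the labels' protocols, nuclei were sonicated and both libraries were sequenced on an Illumina instrument. How the tag was joined to ZFP64 is not given in the sources used here.

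The submitters' processing notes name Bowtie2 2.4.1, SAMtools, MACS2 2.2.7.1 and deepTools 3.5.0, with no role or order, and the genome build hg38. The 4 deposited tables are an annotated list of narrow peaks, 2 smaller peak lists and a table of gene identifiers. Each peak carries the fold, a ratio of ChIP over background at the summit, as the authors deposited it. Each peak also carries the p-value and q-value that the authors deposited, which are read here as comparing these 2 libraries, not 2 conditions. Genomic class, nearest gene and distance to the transcription start are the authors' deposited annotation. The tool behind the annotation, the treatment of duplicate reads and the read layout are not given in the sources used here. With 1 Flag ChIP library, no pooling of replicates arises.

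Chromosome positions are those of the deposited list, in hg38. Genes were counted against a RefSeq gene table of the GRCh38 assembly, which gives no strand and no exons. Of 5246 genes assigned to peaks, 5231 were found in it by gene identifier. The background for gene lists was the 19974 protein-coding genes on chromosomes 1 to 22 and X. Shares have exact binomial (Clopper-Pearson) 95% intervals and counts exact Poisson 95% intervals, which cover counting error only. For a list with 0 members that had a promoter peak, the upper limit is 3 counts of its total. The difference of median fold between classes has a bootstrap interval from 10000 draws over peaks.

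A total read count for each library was not used here, so depth was read from the peaks. The deposited fold and p-value were solved together for a whole number of ChIP fragments and an expected background at the summit, under the peak caller's Poisson model with a pseudocount of 1. Of 6302 peaks with a p-value above 0, 6300 (99.97%) gave a whole number within 0.001 on the −log10 p scale. The lowest background was 1.47 fragments, read as the genome-wide floor. Away from the floor and under 10 fragments, 100% of backgrounds lay on whole steps of a fragment, 1 kb or 10 kb input window (tolerance 3e-05), against 0.755% of random values. These steps gave 3.05 input fragments per ChIP fragment, a mean fragment of 264 bp, and 5568 ChIP fragments per Mb of effective genome. The recovery is an inference from that model and was chosen after the data were examined. A first, wider search for the step had settled on a value that fitted few backgrounds, and the narrower search ranges, 0.3 to 0.36 and 0.075 to 0.1, were set after looking at the backgrounds.

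Lists of genes were fixed before the data were examined. They cover macrophage-directed cytokines and chemokines, macrophage markers, immune checkpoint ligands and antigen presentation, protein kinase C genes with the protein kinase D genes, KMT2A with its partners and targets, the Notch pathway, the NF-kappaB and Toll-like receptor pathway, hepatocyte identity, hepatocellular carcinoma drivers and markers, cytosolic ribosomal proteins, oxidative phosphorylation, cell cycle and DNA replication, glycolysis, replication-dependent histone genes, ZNF zinc finger genes, olfactory receptors, and keratinocyte and erythroid markers. For each list, the members with a promoter peak (within 3 kb of a start) were counted and placed among 10000 random lists of the same size. Such members are called bound, a word that here names a peak only and does not show that ZFP64 was there. Percentiles above 97.5 or below 2.5 are called above or below the random range. Chance gives this for 5% of lists if every gene is equally likely to have a promoter peak. The random lists include silent genes and were not matched on promoter GC content, since no genome sequence was used here. Fisher's exact test (two-sided, Benjamini-Hochberg over the 17 lists, threshold 0.05) was an alternative.

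The rule for named genes was also fixed beforehand. It takes CSF1, ZFP64 and PRKCA, the 10 protein-coding genes with the highest fold at a promoter peak, the 5 highest peaks outside promoters, up to 3 members per list by fold, all bound members of the macrophage-directed cytokine list, and up to 5 genes with at least 4 peaks. Genes outside the rule are marked where they appear. A result that the rule takes is not reported here.

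Random positions kept the chromosome and width of each peak, and were compared with the peaks by distance to either end of a gene, since starts could not be told from ends. The planned comparison of sequence under the peaks with their flanks, random positions of equal GC content, and matching of lists on promoter GC were not run. Alternative settings kept only peaks with a fold of at least 5 or a −log10 q of at least 10, changed the promoter window to 1 kb, counted any assigned peak, and replaced the deposited annotation by the gene table.

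On simulated data, the list test called lists given a binding weight of 3 in 98% and 96% of 100 simulated sets over the 19974 genes, and a list of weight 2 in 48%. Unchanged lists fell outside the range in 5.25%. All genes outside the raised lists had the same weight, so this share was set by the simulation. In the data, a promoter peak was found at 10.5% of genes in the shortest of 5 length bins and 29.8% in the longest. The share of chance calls there is not shown. The recovery returned the true count in 100% of 707 simulated peaks. Those peaks were made under the same model, so this does not test whether the deposited values follow it. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.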

Results

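Flag chromatin immunoprecipitation sequencing was used to map ZFP64 in PLC/PRF/5 liver cancer cells that overexpress it, with 1 Flag ChIP library and 1 input library. The series title places ZFP64 between protein kinase C alpha, encoded by PRKCA, and CSF1, the growth factor that recruits and sustains macrophages. The question put to the peak list was therefore where the Flag ChIP was enriched, and whether the CSF1 promoter was among its sites. Without a Flag ChIP from cells lacking the tag, no peak, KMT2A included, can be separated from nonspecific signal of the antibody. With 1 library per kind, no value below has a replicate error, and intervals cover counting error or the spread between peaks.

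The deposited list held 6373 peaks on 23 chromosomes, covering 4286 kb. KMT2A and ZFP64 itself had the highest folds, 755 and 324, while the median peak had a fold of 6.56 (quartiles 4.87 to 10.6). A fold of at least 10 was reached by 1758 peaks and a fold of at least 100 by 23. Peaks had a median width of 506 bp (quartiles 361 to 818, range 263 to 3796). The highest q-value in the list was 0.0465. Fold, p-value and q-value are the authors' own for each peak. Recovered from them, the median peak held 20 ChIP fragments at its summit (quartiles 14 to 32, minimum 8) over a median background of 1.99.

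**Figure D1:**
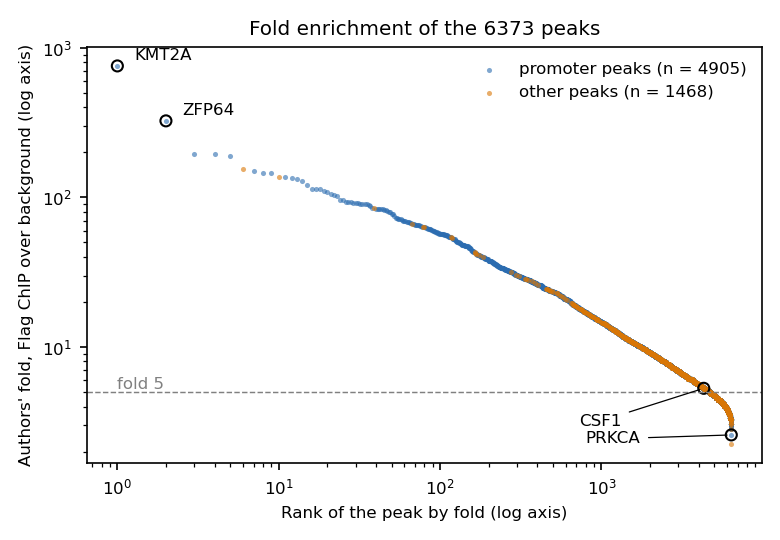
Each point is 1 of the 6373 peaks, placed by its rank (log axis) and its deposited fold of Flag ChIP over background (log axis), with promoter and other peaks in separate colours and a dashed line at a fold of 5. KMT2A (755) and ZFP64 (324) stand at the top, CSF1 (5.30) at rank 4303 and PRKCA (2.58) at rank 6372.

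CSF1 had 1 peak, over an annotated transcription start, with a fold of 5.30 and a q-value of 3.75e-06. It spanned chromosome 1 from 109910973 to 109911289 (hg38, 317 bp), and its summit lay 111 bp downstream of that start, at 109910986. In the RefSeq gene table the gene begins at 109910506, 467 bp before the peak. The recovered counts were 13 ChIP fragments (exact Poisson 95% interval 6.92 to 22.2) over a background of 1.64, a ratio of 7.91 (4.21 to 13.5). The interval of the ratio takes the background as fixed. It also does not allow for the choice of the summit as the highest point of the peak. It ranked 4303 of 6373 peaks and 3437 of 4905 promoter peaks, so that 29.8% of promoter peaks had a lower fold, while 12.4% had fewer fragments at the summit and, among those with a fold of at least 5, 7.17% had a lower fold. No other peak lay within 100 kb of the gene. The peak was absent from the list restricted to a −log10 q of at least 10.

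The other genes of the axis lay at opposite ends of the ranking. The ZFP64 promoter, on chromosome 20 from 52190492 to 52192664, had the second highest fold of the list, 324. A further peak, over another annotated ZFP64 start, from 52105350 to 52105814 had a fold of 8.44 and a q-value of 1.58e-20, with 33 fragments (22.7 to 46.3) over a background of 3.03. PRKCA had a promoter peak on chromosome 17 from 66302811 to 66303521, with a fold of 2.58, the lowest of the promoter peaks. Its q-value, 0.0465, was the highest of the list, with 16 fragments (9.15 to 26.0) over a background of 5.58.

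**Figure D2:**
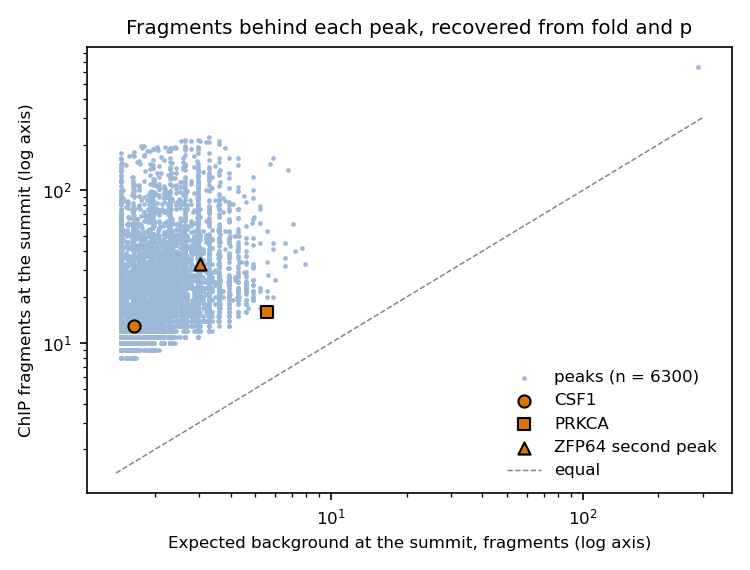
Each point is 1 of the 6300 peaks whose counts could be recovered, placed by its expected background (log axis) and its ChIP fragments at the summit (log axis), with a dashed line where both are equal. CSF1 lies at 13 fragments over 1.64, PRKCA at 16 over 5.58 and the lower ZFP64 peak at 33 over 3.03.

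Among promoters, the strongest peak lay at KMT2A, which encodes a histone methyltransferase, on chromosome 11 from 118434962 to 118437767. Its fold of 755 was 2.33 times that of ZFP64. The next were CDIP1 (fold 195), APBA2 (194), the kinase STK24 (188), the zinc finger gene ZNF76 (149), SYNE2 (145), EOGT (144), SNX12 (136) and PRPSAP1 (135). The peaks of all 10 genes overlapped the transcription start, and all had a q-value deposited as 0. Outside promoters, the highest folds were assigned to SP9 (154, 5059 bp from its start), METTL2B (136, 37470 bp), the cell cycle kinase WEE1 (84.5, 26624 bp), the microRNA gene MIR183 (66.7) and an intron assigned to LINC00467 (63.7, 16817 bp). At least 4 peaks were assigned to each of 38 genes, led by the corepressor gene BCOR with 7 peaks (highest fold 42.8, in an intron). TNRC18 (32.8) and YWHAZ (18.6, 16298 bp from its start) had 6 peaks each. SMAD6, which encodes an inhibitory SMAD, had 5 peaks (42.1, 130401 bp from its start). Its promoter peak had a fold of 7.33. Assignment to a gene is by nearness and does not show that the site acts on that gene.

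Most peaks lay at promoters. Of the 6373 peaks, 4905 (77.0%, 75.9 to 78.0) were annotated to a promoter, 4552 of them within 1 kb of the start. Introns held 666 (10.5%, 9.71 to 11.2) and distal intergenic regions 627 (9.84%, 9.12 to 10.6). Exons held 106, 3′ untranslated regions 38, regions downstream of genes 27 and 5′ untranslated regions 4. Each peak has 1 class, and all 4905 peaks within 3 kb of a start were classed as promoter. The other classes therefore leave out exons, introns and 5′ untranslated regions near a start. The transcription start was overlapped by 2969 peaks (46.6%), and 954 (15.0%) lay over 10 kb from the nearest start. Promoter summits lay a median of 179 bp downstream of the start (quartiles -102 to 389), and 69.5% (68.1 to 70.7) lay downstream. Peaks within 3 kb of either end of a protein-coding gene made up 67.9%, against a mean of 8.25% for 1000 sets of random positions (range 7.08 to 9.29), a ratio of 8.24. Peaks outside promoters lay within 3 kb of either end of a gene of any type in 28.6% (26.3 to 31.0), against 17.7% for random positions (15.1 to 20.8). Starts were not told from ends here. Unlike these peaks, the random positions were not kept outside promoters, so the 2 shares describe unlike sets. Random positions were not matched on GC content or on how readily reads map.

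**Figure D3:**
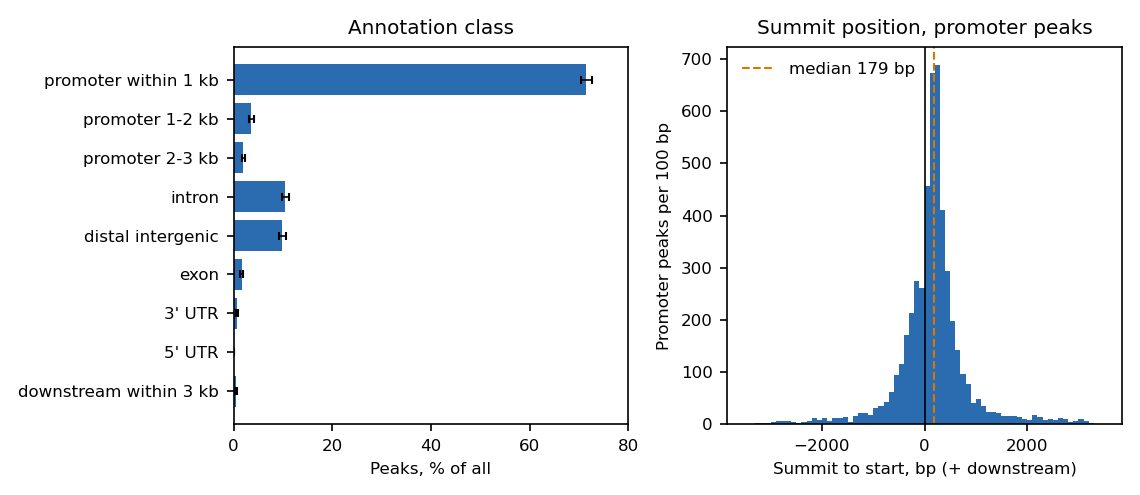
Left, bars give the share of all 6373 peaks in each annotation class (%), with exact binomial 95% intervals. Right, bars give the number of promoter peaks per 100 bp of distance from summit to transcription start (bp, positive downstream), with a solid line at the start and a dashed line at the median of 179 bp.

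Promoter peaks had higher folds than other peaks. The median fold was 6.98 (quartiles 5.05 to 11.7) for the 4905 promoter peaks and 5.76 (4.55 to 7.89) for the 1468 others, a difference of 1.21 (bootstrap 95% interval 0.972 to 1.44). A fold of at least 10 was reached by 31.5% of promoter peaks and 14.6% of the others. Wide peaks also had high folds across peaks (Spearman's rho 0.689), and peaks are not independent replicates.

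A promoter peak was found at 4049 of the 19974 protein-coding genes (20.3%). Of the 17 fixed lists, 5 lay above the random range, 5 below and 7 within. Among hepatocellular carcinoma drivers and markers, 19 of 37 had a promoter peak against a mean of 7.46 in random lists (percentile 100). They were led by the antioxidant regulator NFE2L2 (39.7), the GTPase gene HRAS (32.1) and the chromatin remodelling gene ARID2 (26.0). KMT2A with its partners and targets had 14 of 28 (random mean 5.65, percentile 99.97), with KMT2A (755), KMT2B (32.5) and HOXA5 (23.1) highest. Of the glycolysis genes 11 of 26 had a promoter peak (5.28, percentile 99.4), with PDK1 (41.5), PFKFB3 (24.7) and ENO1 (12.6) highest.

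The protein kinase C list, which also holds the 3 protein kinase D genes, had 7 of 12 members with a promoter peak (random mean 2.42, percentile 99.7), with PRKCE (9.93), PRKCH (8.47) and the protein kinase D gene PRKD3 (6.34) highest. The PRKCE value is that of a peak on chromosome 2 from 46072867 to 46073238. A further PRKCE peak, over another annotated start, from 45650006 to 45651568, had a fold of 6.07, below PRKCH and PRKD3. All 3 protein kinase D genes had a promoter peak, and the 9 protein kinase C genes alone had 4 (1.83, percentile 94.2), inside the range. The percentile of the whole list was 71.9 with a −log10 q of at least 10 and 97.4 with peaks within 3 kb of either gene end, both inside the range. The Notch pathway had 12 of 32 (6.49, percentile 98.7), with the coactivator MAML3 (29.4), the target gene HES1 (26.3) and the ligand JAG1 (13.5) highest. Its percentile was 88.8 with a window of 1 kb, 72.9 with peaks near either gene end and 97.4 without peaks of over 2 times the median background, all inside the range.

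Macrophage-directed cytokines and chemokines, the list that holds CSF1, lay within the random range, with 8 of 33 members (random mean 6.67, percentile 72.2). The bound members were MDK (23.5), CXCL2 (10.3), CXCL1 (9.43), IL11 (7.79), CXCL16 (5.68), CSF1 (5.30), VEGFA (4.67) and MIF (4.46). Immune checkpoint and antigen presentation genes had 11 of 33 (6.69, percentile 96.1), led by PSMB9 (12.4), NT5E (10.2) and IFNGR2 (9.85). Their percentile was 98.0 with any assigned peak counted and 99.7 with peaks near either gene end, both above the range. It was 66.1 with a fold of at least 5 and 87.2 with a −log10 q of at least 10, both inside the range. Without peaks of over 2 times the median background it was 92.7, also inside. The NF-kappaB and Toll-like receptor pathway had 10 of 35 (7.09, percentile 88.1), led by MAP3K7 (17.1), TRAF3 (15.5) and NFKB1 (14.2). With peaks near either gene end, it had 15 of 35 and lay above the range (percentile 99.3). Hepatocyte identity genes had 9 of 34 (6.88, percentile 81.0), led by FOXA1 (21.1), PPARA (15.5) and FOXA2 (14.1). Cell cycle genes had 11 of 40 (8.12, percentile 86.6), led by TYMS (28.9), WEE1 (16.4) and CDKN1A (15.8). Oxidative phosphorylation genes had 13 of 72 (14.6, percentile 32.6), led by NDUFB6 (12.9), COX5A (10.6) and ATP5MC1 (10.03). Cytosolic ribosomal protein genes had 17 of 78 (15.8, percentile 64.2), led by RPS18 (62.5), RPLP1 (13.3) and RPL12 (9.78). Their percentile was 99.1 against random lists matched on gene length and number of transcripts, above the range. With peaks near either gene end, they had 30 of 78 (percentile 99.8), also above the range. The deposited annotation names only the nearest gene for each peak, so a gene sharing that promoter can be counted as unbound. How many list members were missed in this way was not examined.

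The lists below the random range included genes with roles in other cell types, but also histone and ZNF genes. Expression was not measured here. Olfactory receptors had 1 of 390 (OR4D1, random mean 79.0, percentile 0). Macrophage markers had 0 of 25 (5.02, percentile 0.175), and keratinocyte and erythroid markers 0 of 25 (5.06, percentile 0.21), where a limit of 3 counts allows a share of up to 12% in either list. Replication-dependent histone genes, which are used in dividing cells, had 3 of 69 (14.0, percentile 0): HIST3H2BB (9.27), HIST1H4C (3.79) and HIST1H1B (3.50). ZNF zinc finger genes had 85 of 517 (105, percentile 1.24), with ZNF76 (149), ZNF777 (91.9) and ZNF629 (77.8) highest. Matched on gene length and number of transcripts, the percentile was 10.1 for the histone genes and 2.67 for keratinocyte and erythroid markers, both inside the range. For ZNF genes it was 0.315 in that matching, still below the range. Matched on gene density it was 6.14, inside the range, and Fisher's exact test gave an adjusted p of 0.0518.

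**Figure D4:**
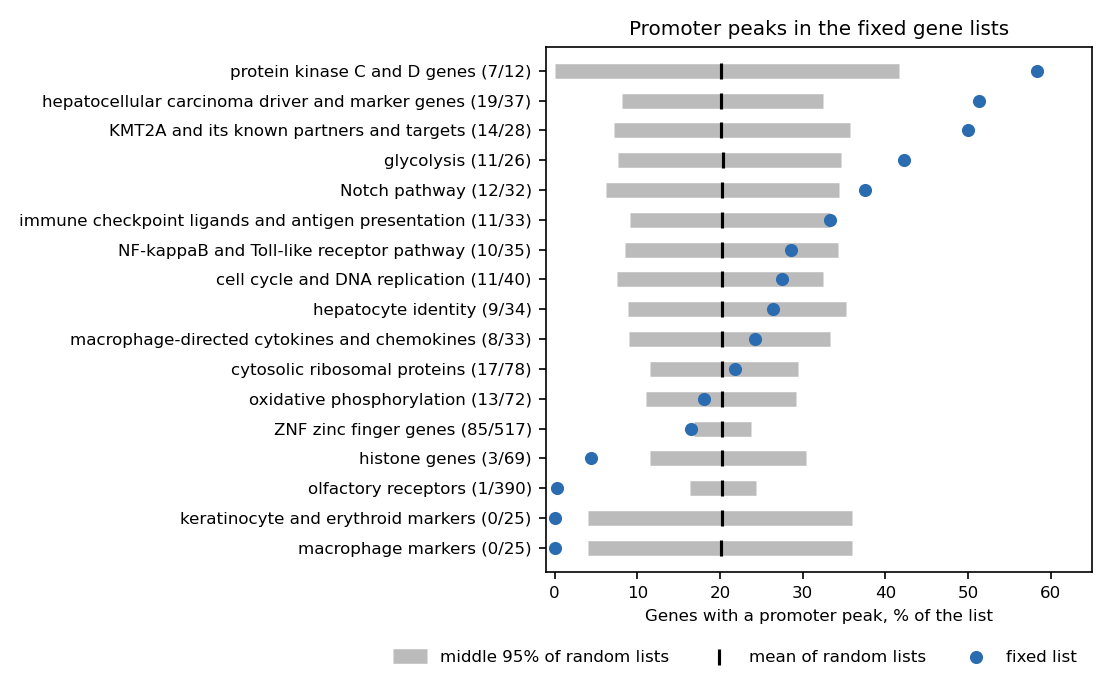
Points give the share of each fixed list with a promoter peak (%), grey bars the middle 95% of 10000 random lists of the same size and vertical marks their mean, with the bound and total members in brackets. The list of protein kinase C and D genes (7 of 12) and the liver cancer list (19 of 37) stand highest, and olfactory receptors (1 of 390) and macrophage markers (0 of 25) near 0.

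The smaller deposited tables narrowed the list by class and fold. The second held the 4905 promoter peaks, and the third the 3708 of them with a fold above 5 (lowest 5.00059, highest left out 4.99872), from 3401 genes. CSF1, at 5.30, was inside it. The fourth table set those 3401 genes beside an unlabelled column of 85 genes, all among them. The rule that selected the 85 is not given in the sources used here. The 85 had a median highest fold of 13.0, against 9.10 for the 3401 genes and 7.72 to 10.6 for random sets of 85 (percentile 99.99). CSF1 ranked 80 of the 85 by fold. Of the fixed lists, the macrophage-directed cytokine list had 1 member among the 85, which was CSF1 itself, and the others 0. With only 85 of the 3401 genes in the column, a count of 1 does not set this list apart from those with 0. Whether these counts differ from chance was not tested. The highest folds of the 85 after ZFP64 were at ADAP1 (132), ERFE (121) and CMPK2 (91.6), chosen after their values were seen.

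Peaks were densest on chromosomes 17 and 19 and sparsest on X and 13. Per Mb of the span covered by genes, chromosome 17 had 5.00 peaks (exact Poisson 95% interval 4.53 to 5.50), 19 had 4.92 (4.37 to 5.52), 13 had 1.01 (0.831 to 1.21) and X had 0.770 (0.638 to 0.920). The highest density was 6.49 times the lowest. The share of protein-coding genes with a promoter peak ordered the chromosomes differently, from 9.43% on X and 13.9% on 19 to 27.4% on 18. The median fold per chromosome lay between 6.06 (chromosome 11) and 7.43 (X).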

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

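Of 256 alternatives over 31 results, 217 left a share or median within its interval, a count within 1.5 times or a list on its side of the threshold, 24 moved the value, 10 ended a call, 5 made one, and none turned the direction of a call. Lists inside the random range did change side of the random mean, as oxidative phosphorylation did (0.889, and 1.20 matched on length and transcripts). The higher fold of promoter peaks held in each alternative run. Matching on gene density or on gene length and transcripts, distances to either gene end for lists, the summit window, removal of peaks with over 2 times the median background, leaving out protein kinase D genes, and ranks by q, fragments or all peaks were chosen after seeing the data. The cause of each change was not tested, except that stricter thresholds keep fewer peaks. A fold of at least 5 gave a median fold of 8.21, a median width of 604.5 bp, promoter, intron and intergenic shares of 79.6%, 9.25% and 8.72%, and 74.8% and 86.9% of peaks within 1 kb and 10 kb of a start. Then 7.17% of promoter peaks lay below CSF1 in fold. A −log10 q of at least 10 left 3175 peaks, 0 of them at CSF1, with a median fold of 10.6, a median width of 743 bp, class shares of 83.5%, 7.59% and 6.83%, and 79.5% and 89.5% within 1 kb and 10 kb. It brought the protein kinase C and D list to 1.45 times the random mean. Measured to either gene end, 75.1% of summits lay within 3 kb, and 63.5% and 86.7% of peak centres within 1 kb and 10 kb. The share below CSF1 was 32.4% among all peaks, 24.1% by q-value and 12.4% by fragments. The remaining values are observed members over the random mean. Peaks near either gene end gave 1.92 for checkpoint genes, 2.11 for protein kinase C and D (call lost), 1.19 for Notch (call lost), 1.81 for NF-kappaB and 1.62 for ribosomal proteins. Checkpoint, NF-kappaB and ribosomal lists then lay above the range. Without the protein kinase D genes, protein kinase C gave 2.18 (call lost). Any assigned peak gave 1.69 for checkpoint genes, above the range. Notch lost its call with a 1 kb window (1.45) and without high-background peaks (1.75). Matching on length and transcripts gave 1.77 for ribosomal proteins (above the range), 0.508 for histone genes and 0 for keratinocyte and erythroid markers, leaving 3 lists below the range. ZNF genes lost their call by Fisher's exact test (0.811) and matched on density (0.864). Sequence under the peaks, random positions of equal GC content, and the class of peak centres by exon or intron were not run, for want of a genome sequence, strand and exons. Lists without GC matching are the values reported. No paired analysis was possible because each group has 1 library. Few fragments lie behind the CSF1 peak (13).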

Other observations

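Some promoter peaks were assigned to genes for RNAs without a protein product. Whether these peaks also lie at the start of an overlapping protein-coding gene was not examined, so they are not shown to be separate sites. Of the 4905 promoter peaks, 4560 were assigned to protein-coding genes, 264 to 256 long noncoding RNA genes, 43 to microRNA genes and 7 to small nucleolar RNA genes. The median fold was 9.77 for the 7 small nucleolar RNA peaks, 7.35 for long noncoding RNA genes, 7.13 for microRNA genes and 6.95 for protein-coding genes, and these differences were not tested. The highest were LOC100294362 (71.5) and LOC101929715 (68.3) among long noncoding RNA genes and MIR1469 (64.5) and MIR4530 (57.3) among microRNA genes. NORAD, a noncoding RNA that binds Pumilio proteins, had a fold of 52.9. These genes were chosen after their values were seen.

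Of the tests that follow, those of promoters used in every cell and of the raised background on chromosome 19, and the count of random lists strictly below, were chosen after the result was seen. The matching on gene length and number of transcripts was also unplanned and was chosen after the data were seen. The design has no second condition, so no explanation by a difference between conditions was tested.

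The lists above the random range may hold long genes with many annotated starts, which give a nearest-gene assignment more chances. Drawn within strata of gene length (5 bins) and number of transcripts (4 bands), the percentiles were 99.87 for KMT2A, 98.98 for Notch, 99.975 for liver cancer genes and 99.1 for glycolysis. All lay above the range, which argues against length and transcripts, as far as these strata match them, as the whole cause for these lists. Genes can still differ inside a stratum, and annotated starts were not counted, so a role of many starts remains open. The protein kinase C and D genes reached 98.5, a percentile that splits ties evenly, but their 7 bound members equalled the upper end of the range (1 to 7) and 97.47% of random lists lay below, so length and transcripts remain open there. Promoters used in every cell are a candidate explanation that remains open. In the same strata, oxidative phosphorylation genes reached percentile 77.1 and ribosomal protein genes 99.1, so lists of widely used genes went different ways. These counts rest on the assignment of each peak to its nearest gene only. With peaks near either gene end and without strata, the percentiles were 86.2 for oxidative phosphorylation and 99.8 for ribosomal protein genes.

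The share of genes with a promoter peak ran from 9.43% on X to 27.4% on chromosome 18, and the number of DNA copies per chromosome may contribute. Across 23 chromosomes, this share and the median background at non-promoter peaks, used as a measure of copies, had a Spearman's rho of -0.134 (two-sided permutation p = 0.542) and a Pearson's r of -0.0474 (permutation p = 0.832). Without chromosomes 4 and 18, farthest from the median background, rho was 0.0809 and r was 0.156. The background cannot fall below the genome-wide floor of 1.47, and the medians of chromosomes 4 and 18, 1.51 and 1.48, lay near it. The share of recovered peaks at the floor ran from 1.28% on chromosome 21 to 42.9% on X. Low copy numbers are therefore poorly measured by this background, which limits the test. The bootstrap interval of rho, -0.542 to 0.333, spans 0, so copies cannot be told apart from no relation. The requirement that this interval lie at or under 0 before copies were excluded was added after rho was seen.

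On chromosome 19 from 19033019 to 19406810, 6 consecutive peaks, at SUGP2, SLC25A42, BORCS8-MEF2B, NCAN and GATAD2A, had backgrounds of 4.90 to 7.70 fragments. A run as long came in a share of 0 of 1000 shuffles of peak order within chromosomes, where the longest was 4, which argues against repeated sequences scattered independently of each other, while repeats that lie in clusters stay open. Extra DNA copies of the interval are a candidate explanation: the median background of the run was 2.92 times that of the chromosome. They cannot be told apart from other sources of raised input, because the run was picked for its high background and the input between peaks was not analysed here. The highest background of the list, 287 fragments, lay at a single peak of fold 2.23.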
